A study of Homo sapiens with 20 samples.

How the data were processed

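Liver RNA of 20 patients with hepatocellular carcinoma was measured on 20 spotted cDNA arrays, 9 from livers named metastasis-inclined microenvironment (MIM) and 11 from livers named metastasis-averse microenvironment (MAM). Per the labels, each array compared patient RNA carrying the dye Cy5 with 1 common reference carrying Cy3, a pool of RNA from 8 normal livers. No array had the dyes swapped. The labels named the tissue as liver, without spelling out whether tumour or surrounding tissue was taken. Every patient code in the array titles ended in N, which could mean non-tumour liver, but its meaning was not given. Each patient had 1 array, so p-values measured the spread between patients.

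The authors deposited 1 table of log ratios, analysed here as log2 values. The scanner files were not used here, and the background correction, spot filters and normalization behind the table were not given in the sources used here. The base of the logarithm was not stated either. The values ran from -9.009 to 7.551, too wide for log10 of a scanner's range, and natural logarithms could not be excluded, in which case every fold printed here would be too small while tests and directions would stay as they are. Medians of the deposited columns lay between 0.0035 and 0.049, so the arrays had been centred close to 0 by a method not stated. The direction of the ratio was not stated; patient over pool was taken as likely, because patient RNA was the measured channel of a common reference design. All 190 pairs of arrays correlated above 0 across genes (lowest r 0.374), so the arrays ran the same way. If the ratio were turned, every sign and every higher or lower in the text would turn with it. A check planned on matrix genes against the normal pool did not settle the direction, since they went both ways.

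The table held 9128 probes with 0 missing values. A platform annotation gave 6318 probes 1 gene symbol, 106 several and 2704 none, and 6315 of the probes with 1 symbol were matched by gene ID to the GRCh38.p14 gene table for current symbols. Probes of the Y chromosome, XIST and TSIX (10 probes) were left out before any test. Probes sharing 1 symbol were averaged on each array, which left 8624 rows, 5814 named genes and 2810 single probes without 1 symbol. Averaging joined more than 1 probe for 462 genes, and among the 242 genes chosen for naming, 17 had more than 1 probe, of which 6 had probes of opposite sign against the pool.

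Each row was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, all 20 arrays, a mean for each group). MIM was tested against MAM, and the mean of both groups, MIM alone and MAM alone were tested against 0, that is, against the pool. Benjamini-Hochberg adjusted p-values under 0.05 were called. The pool is 1 control sample on 1 dye. Tests against it therefore left out the spread between normal livers and could not separate a dye effect. Pool and dye cancel in MIM minus MAM only where arrays of both groups carry them at the same scale. The slope of the arrays on the mean profile of all arrays was 0.81 in MIM and 1.16 in MAM, so they may not cancel fully. Tests of 33 gene lists used limma's cameraPR on the moderated statistics, two-sided, with a preset inter-gene correlation of 0.01, for lists with at least 5 measured genes. Exact two-sided permutation tests went through all 167960 divisions of the 20 arrays into 9 and 11. Errors are SD between arrays or, for differences, the SE of the limma fit.

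Groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text drew on the 12 highest and 12 lowest differences among called genes with 1 symbol for MIM against MAM, the 10 highest and 10 lowest for patients against the pool, 4 members of each list with the smallest p, and every measured member of a published 17-gene immune signature. Arrays carried a letter, a or b, and an identifier in their titles, and the identifiers fell into 5 runs; what letter and run stand for was not given. Letter a held 4 MIM and 9 MAM arrays, and letter b 5 MIM and 2 MAM. Runs 2, 3 and 4 held both groups (2 and 2, 3 and 2, 3 and 3 MIM and MAM arrays), run 1 held 1 MIM array and run 5 held 4 MAM arrays. Letter and run were each tried as a block. Differences were also taken within the letters and within runs 2, 3 and 4, making 5 within-batch comparisons. These reuse the same arrays and are not independent of each other. In runs 2 and 3 all MIM arrays were letter b and MAM arrays held both letters. Run 4 was all letter a. Letter a included the MAM arrays of run 5, which held no MIM array. Given the group, 0 genes differed by letter or by run after adjustment in limma, with 260 and 176 genes at an unadjusted p under 0.05.

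Alternatives covered array centring, quantile normalization, scaling of spread, filters, probe handling, variance models, array weights, robust regression, thresholds, other list tests and leaving out each array. The gene test was tested on simulated data with the spread of the real 8624 genes, 50 changed genes at each size. For MIM against MAM it recovered 54% of log2 changes of 0.5, 96% of changes of 1 and 100% of changes of 1.5 and of 2, with 7 false calls among 182. The simulated noise was independent between genes and equally wide in both groups, without letter or run effects. Its false calls therefore do not bound those in the real data. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.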

Results

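Gene expression was measured in the livers of 20 patients with hepatocellular carcinoma, 9 in the MIM group and 11 in the MAM group, each against a common pool of 8 normal livers. Values are log2 ratios, likely patient liver over normal pool, and every sign below would turn if the ratio ran the other way. The design compares livers inclined to metastasis with livers averse to it, and both with normal liver. All 190 pairs of arrays correlated positively across genes, with a median r of 0.785. Log ratios were wider on the MAM arrays. Their median absolute deviation was 0.666 ± 0.261 (SD, n = 11) against 0.445 ± 0.080 (SD, n = 9) on the MIM arrays, an exact permutation p of 0.0160. The slope of each array on the mean profile of all arrays was 1.16 ± 0.36 in MAM and 0.81 ± 0.18 in MIM (exact permutation p = 0.0176). This slope was lower in MIM within letters a and b, by -0.41 and -0.18, and within runs 2, 3 and 4, by -0.13, -0.48 and -0.39.

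**Figure D1:**
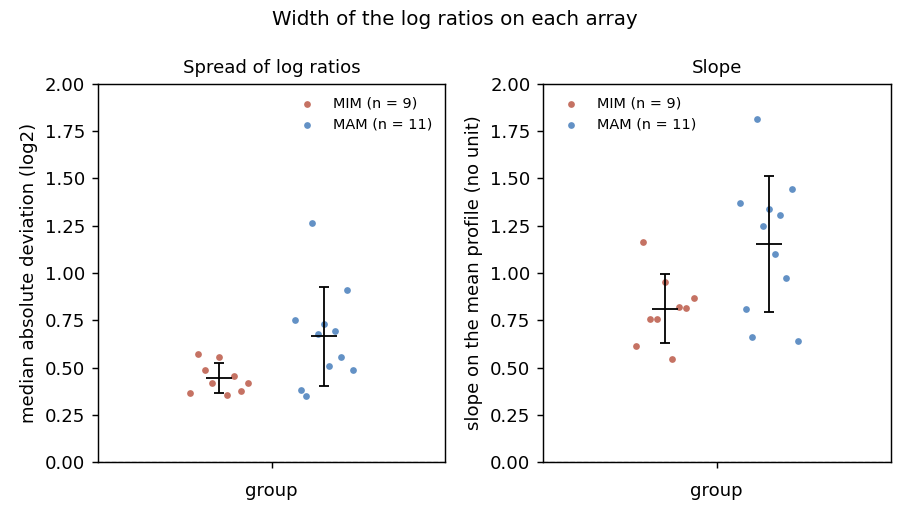
Each point is 1 array, with its median absolute deviation of log2 ratios on the left and its slope on the mean profile of all 20 arrays (no unit) on the right; black bars give the mean and SD of 9 MIM and 11 MAM arrays. The MAM arrays reached a median absolute deviation of 1.26 and a slope of 1.81, while no MIM array passed 0.572 or 1.16.

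The survival factor MCL1, an anti-apoptotic member of the BCL2 family, was the gene with the smallest p between the groups. Its log2 ratio was 0.67 ± 0.50 (SD, n = 9) in MIM and -0.83 ± 0.38 (SD, n = 11) in MAM, a difference of 1.5 ± 0.18 (SE) or 2.83-fold (adjusted p = 0.000281). SRGN, the core protein of proteoglycans stored in granules of blood cells, was higher in MIM by 1.62 ± 0.28 (adjusted p = 0.00776), and the constitutive chaperone HSPA8 by 1.57 ± 0.28 (adjusted p = 0.00798). Lactate dehydrogenase LDHA was higher by 1.56 ± 0.30, and the cytoskeletal genes ACTG1 and ACTR3 by 1.44 ± 0.25 and 1.5 ± 0.30. Among genes lower in MIM, PGM2L1, which makes glucose 1,6-bisphosphate, differed by -0.76 ± 0.15 (adjusted p = 0.0108), and the cornified envelope gene SPRR1A by -0.74 ± 0.18 (adjusted p = 0.0147).

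CRP, the classical acute phase protein, was also higher in MIM by 1.93 ± 0.54 (adjusted p = 0.0250), lying at -2.48 in MIM and -4.41 in MAM. IGFBP1, a liver-made binder of insulin-like growth factors, was higher by 1.59 ± 0.47 (adjusted p = 0.0294), but by -0.11 within letter b and -0.18 within run 2. TDO2, which starts tryptophan breakdown, was higher by 1.5 ± 0.42, and CYP3A7, a cytochrome P450 of fetal liver, by 1.43 ± 0.38. The matrix glycoprotein THBS1 was higher by 1.46 ± 0.33 and the RNA helicase DDX3X by 1.48 ± 0.27. On array MIM 5, ACTR3 and DDX3X stood at -1.88 and -2.22, apart from the rest of their group. The 12 with the lowest differences ran from -0.77 for ANKRD29 to -0.65 for CHTOP. Between them lay POGZ, B3GAT1, C14orf119, CTTNBP2, ATCAY, the DNA repair gene XRCC4, the ciliary transport gene IFT52 and the sodium channel gene SCN7A. ANKRD29 stood at -1.09 on array MIM 6, apart from the other MIM arrays. The means of all 12 lay above the pool in both groups, further in MAM, as for POGZ at 1.27 in MIM and 1.98 in MAM. Lower in MIM thus meant closer to the pool for them. Across all genes, MIM minus MAM correlated with the mean of both groups against the pool at -0.620, and at -0.115 after quantile normalization.

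In all, 1432 of 8624 genes and probes differed between MIM and MAM by limma at an adjusted p under 0.05, 830 higher and 602 lower in MIM. Of these, 438 differed at least 1.5-fold (375 higher, 63 lower), 75 at least 2-fold, and 612 of the higher and 403 of the lower were named genes. MIM lay above the pool and MAM below it for 274 of the 1432, and the other way round for 227. Within the letters and runs, MCL1 differed by 1.46 and 1.51 in letters a and b and by 1.72, 1.44 and 1.07 in runs 2, 3 and 4. With the letter as a block 7 genes were called and with the run as a block 2, MCL1 in both (adjusted p = 0.00290 and 0.0418). The count also fell to 921 (519 higher, 402 lower) with arrays scaled to one spread, which left 11 of the 12 highest and 1 of the 12 lowest genes past the threshold, and to 911 (430 higher, 481 lower) with array slopes removed, which left 11 of the highest, CRP not among them (adjusted p = 0.392), and 6 of the lowest. It ran from 490 without MIM 3 to 2191 without MAM 3 when 1 array was left out.

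**Figure D2:**
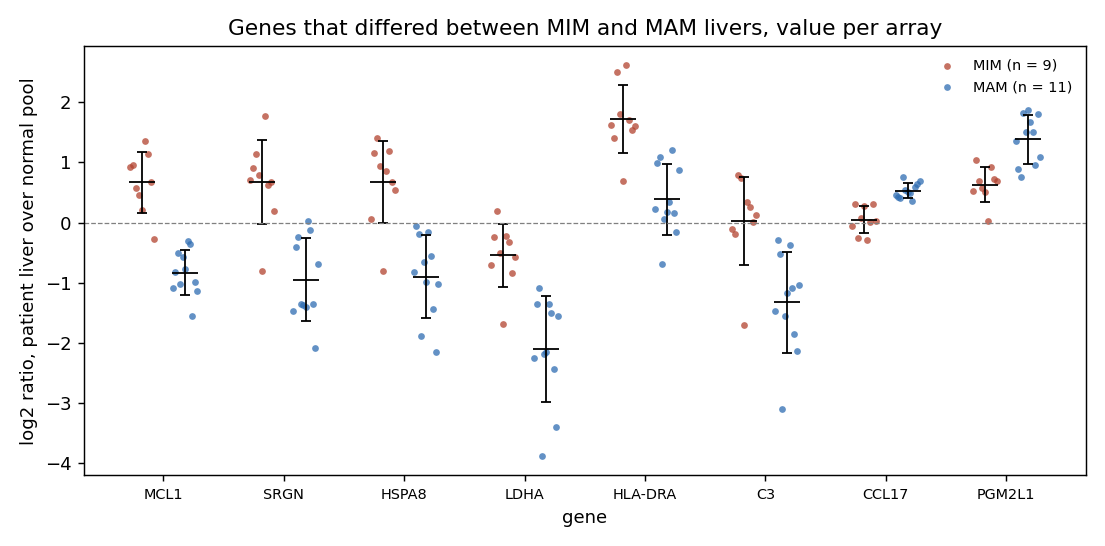
Each point is the log2 ratio (likely patient liver over normal pool) of 1 gene on 1 array, with mean and SD of the 9 MIM and 11 MAM arrays in black. CCL17 lay between -0.288 and 0.316 on the MIM arrays and between 0.352 and 0.751 on the MAM arrays, and MCL1 between -0.277 and 1.364 on the MIM arrays and between -1.553 and -0.312 on the MAM arrays, so the groups did not overlap for either gene. Both were chosen on these same arrays, so the gap is not independent evidence. Of the genes shown, MCL1 alone was called with the letter or the run as a block.

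As lists, genes of MHC class II antigen presentation and of macrophages were higher in MIM (each with an adjusted p of 0.232 with an estimated correlation). The class II chain HLA-DRA stood at 1.72 ± 0.57 (SD, n = 9) in MIM and 0.39 ± 0.59 (SD, n = 11) in MAM, a difference of 1.34 ± 0.24 (adjusted p = 0.00798). Of 13 measured class II genes 4 were higher, 0 lower and 9 did not pass over all genes, and 5 passed adjusted over the list alone. The lysosomal protease CTSS was higher by 1.03, HLA-DRB5 by 0.84 and the class II transactivator CIITA by 0.34. The list passed cameraPR (adjusted p = 0.000922; adjusted p = 0.232 with an estimated correlation). Macrophage and Kupffer cell markers were higher for 7 of 14 measured genes, 9 adjusted over the list alone, among them the endotoxin co-receptor CD14 (0.42), the Fc receptor chain FCER1G (0.49) and the integrin ITGAM (0.41). CIITA and ITGAM did not pass with array slopes removed (adjusted p = 0.437 and 0.134). That list had an adjusted p of 0.00421, and an adjusted p of 0.232 with an estimated correlation. List means differed by 0.39 for class II and 0.30 for macrophages, by 0.29 to 0.48 and 0.24 to 0.33 in the 5 within-batch comparisons, and by 0.35 and 0.26 with the letter or 0.38 and 0.28 with the run as a block.

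Markers of other leukocytes did not pass as lists. Mean differences were -0.0027 for 20 T and NK cell genes (adjusted p = 0.978), where the sign turned with the letter or the run as a block, and, with signs that turned after quantile normalization, 0.039 for 10 B and plasma cell genes (adjusted p = 0.978) and 0.030 for 15 neutrophil and mast cell genes (adjusted p = 0.872). Single members went both ways: NKG7 and CD8B were higher in MIM by 0.55 and 0.41, while the cytotoxic granule protease GZMB was lower by -0.41. TCL1A, a B cell gene, was lower by -0.44, and the mast cell receptor KIT by -0.42. Adjusted over the list alone, 3, 4 and 3 members of these lists passed.

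Of the published 17-gene immune signature 8 genes were measured, and since the study chose that list on these samples, its count is not independent evidence. Over all genes SRGN, HLA-DRA and IL12A (0.54 ± 0.13, adjusted p = 0.0165) were higher in MIM and IL2 was lower (-0.39 ± 0.12, adjusted p = 0.0306). The chemokine CXCL8 (1.57 ± 0.63, adjusted p = 0.0840), TNF (0.65 ± 0.23, adjusted p = 0.0568), IL4 (-0.25, adjusted p = 0.234) and IL10 (0.08, adjusted p = 0.542) did not pass. Adjusted over the list alone, 6 passed, CXCL8 and TNF included. As a list it passed cameraPR with an adjusted p of 0.0155, and had an adjusted p of 0.321 with an estimated correlation. Lists of Th1 (6 genes, adjusted p = 0.778) and Th2 cytokines and receptors (9 genes, adjusted p = 0.315) did not pass. In the latter, the interleukin 10 receptor gene IL10RA was higher in MIM by 0.74 and the antagonist IL1RN by 0.55. Among 15 chemokines (adjusted p = 0.900), CCL17 and CXCL13 were lower by -0.48 and -0.57 and CXCL1 was higher by 0.56.

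Of 11 genes of ER stress and protein folding 7 were higher in MIM and 0 lower, 8 adjusted over the list alone, with HSPA5, the main chaperone of that compartment, higher by 1.29 ± 0.28 (adjusted p = 0.0118). The list passed with an adjusted p of 0.000213, and had an adjusted p of 0.232 with an estimated correlation. Of 9 MHC class I presentation genes 4 were higher, 6 adjusted over the list alone (list adjusted p = 0.000935; adjusted p = 0.232 with an estimated correlation). These were CALR (0.84), PDIA3 (0.87), CANX (0.87) and TAPBP (0.39), of which CALR, PDIA3 and CANX fold many glycoproteins besides class I. Among 17 immediate early and heat shock genes 5 were higher, 6 adjusted over the list alone (list adjusted p = 0.000922; adjusted p = 0.232 with an estimated correlation). Those named by rule, HSPA8, DNAJA1 (0.85), HSPH1 (0.65) and HSP90AB1 (0.47), are all chaperones or their partners. With array slopes removed CANX, TAPBP and HSP90AB1 did not pass (adjusted p = 0.0625, 0.0918 and 0.0679). These list means differed by 0.50, 0.47 and 0.39, by 0.36 to 0.64, 0.34 to 0.64 and 0.15 to 0.43 within batches, by 0.44, 0.42 and 0.33 with the letter and by 0.48, 0.46 and 0.37 with the run as a block. They were 0.26, 0.27 and 0.26 with array slopes removed, and 0.28, 0.29 and 0.28 with quantile normalization.

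Of 18 complement genes 8 were higher in MIM and 0 lower, 13 adjusted over the list alone, among them the central component C3 (1.36 ± 0.32, adjusted p = 0.0147) and C6 (1.34), C8B (1.15) and C2 (0.84). The complement list passed with an adjusted p of 0.000422, and had an adjusted p of 0.368 with an estimated correlation. Array MIM 5 held the lowest complement mean of its group, -0.79. The mean of 16 hepatocyte secreted and marker genes, a list that did not pass (adjusted p = 0.0542), differed by 0.39, with within-batch values from -0.04 to 0.60. With quantile normalization the hepatocyte list passed (0.36, adjusted p = 0.0426). Of 13 acute phase genes 8 were higher and 0 lower, 9 adjusted over the list alone, with SERPINA3, haptoglobin HP and hemopexin HPX higher by 1.30, 1.08 and 1.07 and the transcription factor STAT3 by 0.65. This list passed with an adjusted p of 0.000169, had an adjusted p of 0.321 with an estimated correlation, and no longer passed with array slopes removed (0.26, adjusted p = 0.0538), nor did SERPINA3, HP, HPX and STAT3 singly (adjusted p = 0.296, 0.119, 0.0513 and 0.0504). Coagulation genes were higher for 3 of 17, also 3 adjusted over the list alone, namely A2M (1.05), FGA (0.91) and KNG1 (0.75), with a list adjusted p of 0.0103 and an adjusted p of 0.460 with an estimated correlation. The coagulation list no longer passed with array slopes removed (0.22, adjusted p = 0.0752) or with quantile normalization (0.21, adjusted p = 0.0939). With quantile normalization the acute phase list still passed (0.34, adjusted p = 0.0157). Mean differences of complement, acute phase and coagulation genes were 0.50, 0.84 and 0.35, within batches 0.24 to 0.59, 0.53 to 1.10 and -0.04 to 0.56, with the letter as a block 0.48, 0.70 and 0.30 and with the run 0.46, 0.80 and 0.30.

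**Figure D3:**
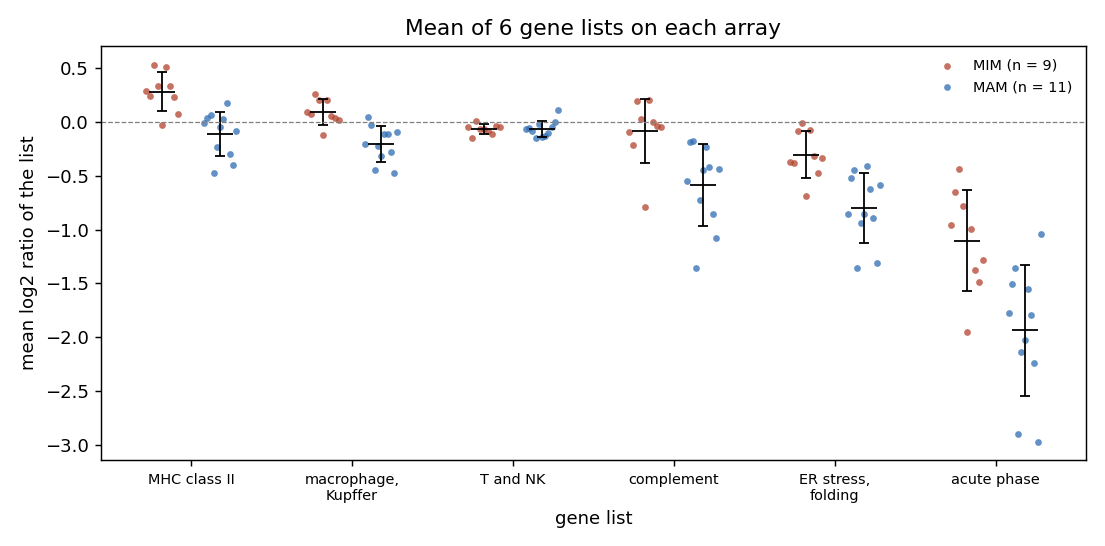
Each point is the mean log2 ratio of 1 gene list on 1 array, with mean and SD of the 9 MIM and 11 MAM arrays in black. MHC class II genes averaged 0.28 in MIM and -0.11 in MAM, acute phase genes -1.10 and -1.94, and T and NK cell genes -0.06 in both groups.

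Urea cycle and amino acid genes were higher in MIM for 4 of 17, also 4 adjusted over the list alone, namely TDO2, arginase ARG1 (1.20), HPD (0.96) and ASL (0.40), and the list passed with an adjusted p of 0.0177 (adjusted p = 0.483 with an estimated correlation). Fatty acid oxidation genes were higher for 4 of 18 and lower for 2, 8 adjusted over the list alone, with HADHA and HADHB, the chains of the mitochondrial trifunctional protein, higher by 0.87 and 0.55 (list adjusted p = 0.0318; adjusted p = 0.460 with an estimated correlation). Hypoxia and glycolysis genes were higher for 6 of 17, 7 adjusted over the list alone, led by LDHA, PDK1 (0.46) and NDRG1 (0.45), with a list adjusted p of 0.0318 and an adjusted p of 0.460 with an estimated correlation. Of 9 metallothionein and oxidative stress genes SOD2 (1.00) and TXNRD1 (0.67) were higher, 2 also adjusted over the list alone, and neither is a metallothionein (list adjusted p = 0.0155; adjusted p = 0.368 with an estimated correlation). Of 23 matrix and stellate cell genes 7 were higher and 1 lower, 9 adjusted over the list alone, with THBS1, lumican LUM (1.31) and smooth muscle actin ACTA2 (1.00) among them (list adjusted p = 0.0475; adjusted p = 0.355 with an estimated correlation). Only 13 of 78 listed ribosomal protein genes were measured, of which RPL29 (0.83) and RPL14 (0.74) were higher and RPL37A (-0.34) was lower, 5 passing adjusted over the list alone (list adjusted p = 0.0176; adjusted p = 0.460 with an estimated correlation). Mean differences of these 6 lists, in that order, were 0.40, 0.20, 0.19, 0.34, 0.24 and 0.34. Within batches they spanned -0.03 to 0.67, -0.16 to 0.40, 0.09 to 0.26, 0.13 to 0.35, 0.17 to 0.35 and 0.07 to 0.52, and with the letter as a block they were 0.43, 0.21, 0.17, 0.30, 0.19 and 0.26, with the run 0.30, 0.14, 0.20, 0.23, 0.23 and 0.34. With array slopes removed, ARG1, ASL, HADHB, PDK1, NDRG1, SOD2 and TXNRD1 did not pass (adjusted p = 0.0539, 0.225, 0.0618, 0.0626, 0.0970, 0.190 and 0.0689). With 1 array left out, the matrix list passed in 10 of 20 fits (adjusted p from 0.0230 to 0.0883), not without MIM 3, 4, 5 or 6 or MAM 1, 2, 4, 5, 6 or 9. Fatty acid oxidation did not pass without MIM 6, MAM 4 or MAM 10 (highest adjusted p 0.0728) and hypoxia not without MIM 6 (adjusted p = 0.0544). Without both MAM 4 and MAM 11, urea cycle, fatty acid oxidation and matrix genes did not pass (adjusted p = 0.0683, 0.0925 and 0.0511). Interferon-induced genes, cholangiocyte markers and proteasome subunits, which did not pass with all arrays, passed then (adjusted p = 0.0349, 0.0390 and 0.0390).

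The remaining lists did not pass. Adjusted p-values were 0.0542 for interferon-induced, hepatocyte marker and cholesterol synthesis genes, 0.0549 for oxidative phosphorylation, 0.0710 for cholangiocyte markers, 0.0720 for proteasome subunits and 0.196 for cytochrome P450 genes. They were 0.255 for hepatocellular carcinoma markers, 0.472 for endothelial markers, 0.572 for erythrocyte and platelet genes, 0.900 for matrix proteases and 0.992 for 29 cell cycle genes, and means and medians had opposite signs for the erythrocyte and cell cycle lists. In total 15 of the 33 lists passed, all higher in MIM, and 11 of them with the run as a block, where urea cycle, fatty acid oxidation, metallothionein and matrix genes did not pass (adjusted p = 0.0635, 0.0903, 0.0967 and 0.0524). With the letter as a block 14 lists passed, matrix and ribosomal genes not among them (adjusted p = 0.0936 and 0.050003) and cholesterol synthesis genes added (adjusted p = 0.0200). With an estimated correlation cameraPR passed 0 lists after adjustment and 5 at an unadjusted p under 0.05, fry called 10 of the 33 and the exact permutation test of list means 17, and 11 of 100 divisions of the arrays into 9 and 11, the real one included, gave 15 or more lists. With array slopes removed, which was chosen after seeing the data, 8 lists passed: MHC class II, complement, ER stress, macrophage, 17-gene, MHC class I, heat shock and urea cycle genes. Fatty acid oxidation, hypoxia, metallothionein, matrix and ribosomal genes did not pass then (adjusted p = 0.0848, 0.249, 0.109, 0.109 and 0.0555), nor, but for ribosomal genes, with quantile normalization (adjusted p = 0.0965, 0.213, 0.123 and 0.202).

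As a list, acute phase genes were lower in patient livers than in the normal pool (adjusted p = 3.02e-05; adjusted p = 0.408 with an estimated correlation). Serum amyloid SAA1 stood at -4.33 ± 1.01 (SD, n = 20), CRP at -3.45 ± 1.64, the secreted phospholipase PLA2G2A at -3.22 ± 1.21 and orosomucoid ORM1 at -2.30 ± 0.62, each below 0 on 20 of 20 arrays. The fetal growth factor IGF2 was lower as well, at -2.26 ± 0.29 (adjusted p = 1.54e-17). Highest among named genes were SKAP2, an adaptor of leukocyte signalling, at 3.0 ± 0.61 (adjusted p = 3.06e-15), and TMEM87B at 2.90 ± 0.60, each above 0 on 20 of 20 arrays.

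The other named genes at the top were TRMT61B, YRDC, TMCO4, STEAP2, CAMK4, SMC6, NPR3 and UBE2Q1, between 2.86 and 2.61. Of these, CAMK4 and UBE2Q1 reached 3.68 and 3.61 on array MIM 2, above the other MIM arrays. Lowest, besides those given, were ZNF76 (-3.05), PLCD1 (-2.88), SAA4 (-2.31), SERPINA3 (-2.30) and ATF6B (-2.23). In all 6613 of 8624 genes and probes differed from the pool in limma, 3255 higher and 3358 lower, and 2009 of them by at least 1.5-fold (1617 higher, 392 lower). Since the pool was 1 sample on one dye throughout, dye effects and the makeup of the pool could not be separated from these values, and spread between normal livers is left out.

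Against the pool 7 of 33 lists passed, all lower in patients. Of 13 acute phase genes 10 were lower and 1 higher, 11 adjusted over the list alone, with a list mean of -1.56 ± 0.68 (SD, n = 20) that lay below 0 on 20 of 20 arrays (adjusted p = 3.02e-05; adjusted p = 0.408 with an estimated correlation). Of 16 genes of cholesterol and lipid synthesis 15 were lower and 1 higher, 16 adjusted over the list alone, among them FDPS (-0.81), SQLE (-0.68) and MSMO1 (-1.03), and the list had an adjusted p of 0.000334 (adjusted p = 0.335 with an estimated correlation). Hepatocellular carcinoma markers were lower for 7 of 12 genes and higher for 3, 10 adjusted over the list alone, led by IGF2 and the oncofetal proteoglycan GPC3 (-1.04), while UBD was higher (0.70); the labels did not say whether tumour or surrounding liver was taken. This list had an adjusted p of 0.00296 and alone kept one under the threshold with an estimated correlation (adjusted p = 0.0285). All 11 ER stress genes were lower, HSP90B1 by -0.80 and SEL1L by -0.59, also 11 adjusted over the list alone (adjusted p = 0.00296; adjusted p = 0.441 with an estimated correlation).

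MHC class I genes were lower for 7 of 9 and higher for 1, 8 adjusted over the list alone, led by the peptide transporter TAP2 at -1.36 (list adjusted p = 0.0189; adjusted p = 0.441 with an estimated correlation). Proteasome subunits were lower for 14 of 17 and higher for 1, 15 adjusted over the list alone, PSMA3 by -0.41 (list adjusted p = 0.0482; adjusted p = 0.441 with an estimated correlation). Immediate early and heat shock genes were lower for 11 of 17, 10 adjusted over the list alone, HSPA1A by -0.60 (list adjusted p = 0.0450; adjusted p = 0.592 with an estimated correlation). With 1 array left out, the proteasome list passed in 9 of 20 fits (adjusted p from 0.0395 to 0.0549), not without MIM 2, 5, 8 or 9 or MAM 1, 3, 5, 6, 9, 10 or 11. The heat shock list passed in 14 of 20 (0.0301 to 0.0549), not without MIM 5 or 9 or MAM 5, 9, 10 or 11, nor without both MAM 4 and MAM 11 (adjusted p = 0.0623). With quantile normalization 4 lists passed, and the MHC class I, proteasome and heat shock lists did not (adjusted p = 0.0931, 0.0931 and 0.109). The matrix list did not pass (mean -0.08, adjusted p = 0.359), with the proteoglycan DCN at 1.84 and COL1A1, a chain of type I collagen, at -1.49. MHC class II genes did not pass either (adjusted p = 0.604), HLA-DQA1 standing at 1.72 and CIITA at -0.57, and the mean and median of that list and of the 17-gene signature had opposite signs. Among chemokines CCL11 (1.29) and CXCL10 (1.17) were higher on 20 of 20 arrays and CCL18 (-0.88) lower on 20 of 20.

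Taken group by group against the pool, MCL1, SRGN and HSPA8 were above the pool in MIM and below it in MAM. MCL1 stood at 0.67 in MIM (adjusted p = 0.000305) and -0.83 in MAM (adjusted p = 2.62e-06). The class II gene HLA-DRB5 was at 0.46 in MIM (adjusted p = 0.0374) and -0.38 in MAM (adjusted p = 0.0382). C3 was lower than the pool in MAM (-1.33) and did not pass in MIM (0.03, adjusted p = 0.934), and ACTG1 was at -1.70 in MAM and -0.26 in MIM, where it did not pass (adjusted p = 0.238). IL4 was above the pool in both, at 0.58 in MIM and 0.83 in MAM. MIM differed from the pool for 4468 genes and probes (2609 higher, 1859 lower) and MAM for 6417 (3288 higher, 3129 lower). Those counts come from groups of 9 and 11 arrays and from log ratios that were wider in MAM. With arrays scaled to one median absolute deviation they were 5705 (2822 higher, 2883 lower) and 6091 (3007 higher, 3084 lower), and their difference in size was not tested.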

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

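In the tests of this part, the removal of array slopes for the count of genes was chosen after the result was seen. The other tests were written down before their results, but those with array slopes removed rest on a step chosen after seeing the data. In the 9 MIM arrays, 87 values were tested for an array that stood apart from the rest of its group, and 8 did, where chance gives about 1 in 20, or 4.35; MAM, with 11 arrays, was not tested. On array MIM 5 the complement list stood at -0.79 (others -0.21 to 0.21), the cholesterol and lipid synthesis list at -0.77 (others -0.44 to -0.12), ACTR3 at -1.88 (others -0.25 to 1.06) and DDX3X at -2.22 (others -0.51 to 0.55). Array MIM 3 held the highest mean of ribosomal protein genes, 0.32 (others -0.25 to 0.03), and array MIM 6 the lowest ANKRD29, -1.09 (others 0.32 to 0.92). On array MIM 2, CAMK4 stood at 3.68 (others 1.87 to 2.68) and UBE2Q1 at 3.61 (others 1.80 to 2.67).

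Between MIM and MAM 1432 genes and probes were called. Of 100 divisions of the arrays into 9 and 11, 1, the real one, gave as many, and the highest other gave 0. This argues against chance for that count without excluding it. At an unadjusted p under 0.05 the highest other gave 2901 against 3116, and the divisions left letter and run out of account. Wider log ratios on the MAM arrays were argued against as the whole source, because 911 genes were called after array slopes were removed, of which 738 had been called with the same sign before. Runs of arrays were argued against as the whole source as well: with slopes removed, differences found separately in runs 2, 3 and 4 correlated across genes at a mean of 0.390, above the 0.236 that 95% of 1200 relabellings within runs stayed under (exact permutation p = 0.0125, one-sided). With the letter or the run as a block the median size of the called differences went from 0.493 to 0.452 or 0.471 and their median SE from 0.139 to 0.151 or 0.169, and 7 or 2 genes were called. Letter was not held fixed within runs 2 and 3, so the correlation between these runs could carry a letter effect. A part of the differences may still come from letter, run or array spread, which were not balanced between the groups. The biological difference the groups are named for stays open.

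The acute phase and complement lists, many but not all of whose genes are expressed mainly in hepatocytes, were higher in MIM (adjusted p = 0.321 and 0.368 with an estimated correlation). With array slopes removed the acute phase difference fell from 0.84 to 0.26 (exact permutation p = 0.169), so wider log ratios on the MAM arrays may account for most of it. That step takes out any difference along the mean profile, where acute phase genes lay far below 0 (list mean -1.56). It cannot tell a technical width of the arrays from MAM livers that lie further from the pool. Which of these gave the acute phase difference stays open. With quantile normalization the acute phase difference was 0.34 and the list still passed cameraPR (adjusted p = 0.0157). The complement difference went from 0.50 to 0.34 (exact permutation p = 0.00744), which argues against wider ratios as its whole source. Hepatocyte secreted and marker genes differed by 0.39, and by 0.35 with slopes removed, without passing cameraPR as a list (adjusted p = 0.0542 and 0.0645). With quantile normalization they differed by 0.36 and the list passed (adjusted p = 0.0426). It also passed in 7 of 20 fits without 1 array. Unequal amounts of hepatocyte RNA thus stay open for complement, as does a difference in liver function between the groups.

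MHC class II and macrophage genes, averaged over both lists, were higher in MIM by 0.32 (each list with an adjusted p of 0.232 with an estimated correlation). With array slopes removed the difference was 0.27 (exact permutation p = 0.000196), which argues against wider ratios as its whole source. The 26 genes of these lists exceeded the 45 genes of the T and NK, B and plasma, and neutrophil lists by 0.30 (exact permutation p = 0.000220). The 2 sets shared 0 genes. This contrast set lists that had passed against lists that had not. The 45 genes alone differed by 0.018 (exact permutation p = 0.578), so the measured markers of those cells did not rise as a set. A higher content of every kind of leukocyte is not excluded by this. Signal over background was not in the values used, so flat markers may have gone undetected. A candidate explanation is more macrophages or more active ones in MIM livers, a hypothesis that bulk RNA could not separate. Not every member was higher in MIM. The macrophage marker CD163 stood at 0.25 in MIM and 0.47 in MAM, and HLA-DQA1 at 1.51 and 1.93, and neither difference passed. Of 14 macrophage genes 7 were called higher and 0 lower, and of 13 class II genes 4 and 0. Other cells that carry MHC class II stay open.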

How the results depend on the processing

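Removal of array slopes, alone or with a block, the fit of runs with both groups and the fits without MAM 4 and MAM 11 were chosen after seeing the data. For MIM against MAM (1432 genes), 921 were called with arrays scaled to one median absolute deviation, 950 among the more variable genes (655 higher, 295 lower), 2591 with array weights, 2351 with robust regression, 438 at 1.5-fold or more and 408 at an unadjusted p under 0.001. In limma, 7 were called with the letter and 2 with the run as a block (2253 and 2028 at an unadjusted p under 0.05), 911 with array slopes removed (47.2% higher, against 58.0%), 2 with slopes removed and the run and 9 with slopes removed and the letter as a block, and 1 from the runs with both groups, with the run as a block. Fewer genes were tested among the more variable ones; for the other changes the cause was not tested. Leaving out 1 array gave 490 to 2191 genes: 773 without MIM 1, 490 without MIM 3, 907 without MIM 4, 514 without MIM 6, 853 without MIM 7, 2191 without MAM 3, 949 without MAM 5 and 738 without MAM 10. Median centring (1444), quantile normalization (1091), other variance models (1424 and 1226), single probes (1512) and leaving out MAM 4 and MAM 11 (1123) stayed within 1.5 times. Of the 24 named genes with the highest and lowest differences, 18 passed without any 1 array; of 20 such fits CRP and TDO2 passed in 18, IGFBP1 in 16, B3GAT1 in 19, CTTNBP2 in 10 and IFT52 in 14. More variable genes, or 1.5-fold or more, gave 3482 and 2009 for patients against the pool, 2356 and 1566 for MIM and 3585 and 2879 for MAM, and an unadjusted p under 0.001 gave 2732 for MIM. Without 1 array these counts ran from 6449 to 6665, 3976 to 4861 and 6251 to 6466. Of 15 lists between the groups, 8 passed with slopes removed and 0 with an estimated correlation in cameraPR (5 at an unadjusted p under 0.05, and 10 by fry), and 12 to 19 without 1 array. Of 7 lists against the pool, 4 passed after quantile normalization, 1 with an estimated correlation and 25 by fry, which does not compare a list with other genes, and 5 to 8 without 1 array. Among the 142 genes and 33 lists followed between the groups, and 139 genes and 33 lists against the pool, no called direction turned in these alternatives; within single letters or runs some did, IGFBP1 among them. Named differences between the groups stayed on their side of the threshold in 2489 of 2840 cases when 1 array was left out (292 weaker, 59 stronger) and in 1335 of 2105 under the other alternatives (725 weaker, 45 stronger); for patients against the pool all 2780 and 1058 did. Filters on missing values gave no result of their own, as 0 values were missing. No paired analysis was possible because replicate numbers only name arrays. Signal over background was not in the values used, so what it limits could not be measured.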

Other observations

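The tests of this part were written down before their results were seen. The 15 gene lists that passed between MIM and MAM were not beyond chance as a count, since 11 of 100 divisions of the arrays into 9 and 11, the real one included, gave 15 or more and the highest other gave 21. As a hypothesis, tumour cells with gains of chromosomes 1 and 8 in MIM samples might raise the genes of those chromosomes. The labels did not spell out whether tumour was sampled, and the N that ended every patient code could mean non-tumour liver. The smaller adjusted p of the 2 chromosomes was 0.848 by cameraPR, and the lowest over all autosomes was 0.243 for chromosome 17. The bound set for this test, an adjusted p over the threshold, was a wrong one, because such a p does not limit the size of a shift and the share of tumour cells was not known, so the hypothesis stays open.

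The first principal component held 45.2% of the variance between arrays and the second 13.2%. Array MAM 4 stood furthest out on the first, at 67.0, with MAM 10 next on that side at 38.6. MAM 4 had the widest spread of log ratios (SD 1.28). MAM 11 had the lowest correlation with the mean profile among the MAM arrays (0.718). For those reasons MAM 4 and MAM 11 were left out together in the fits above.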
